A study of Mus musculus with 24 samples.

How the data were processed

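Gene expression was measured in mouse CD8+ T cells with Illumina whole-genome BeadChips on 24 arrays. The T cells came from spleens of DesTCR mice, which carry 1 transgenic T cell receptor. They were cultured with dendritic cells that lack the mannose receptor, together with FcMR, a fusion of the mannose receptor with an antibody Fc part, or with an isotype control. CD8+ T cells were sorted by flow cytometry and lysed in Trizol, and biotin-labelled cRNA was made with the TargetAmp Nano-g kit. Groups were taken from the sample titles: 6 arrays at 0 h, and 3 arrays each for isotype control and FcMR at 4, 18 and 48 h. The labels number the replicates but do not say how independent they are, so every p-value here measures only the spread between these arrays.

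The deposited values are log2 intensities for 45281 probes, from 6.74 to 15.26. Every array had a median of 7.13 and the sorted values of the arrays differed by at most 0.017, so the values are quantile-normalised, as judged from the values themselves. No background subtraction is visible in them, and fold differences of dim genes are therefore compressed. The submitters' notes name Partek without a version or a role. A second deposited table, with 24 columns of intensities and their detection p-values, was not used here because its columns carry no sample label. For that reason a normal-exponential correction with control probes (neqc), a filter on detection p-values and a term for the BeadChip, all planned before the data were examined, could not be run. The deposited log2 values, planned as an alternative, took their place.

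Background was set from the values at 7.30, which is the mode of all values plus 3 SDs of the distribution to its left. A probe entered when it lay above this level on at least 3 arrays, which 16511 probes did. The probe annotation gave 1 gene symbol to 34885 probes, several to 18 and none to 10378. Of the probes that entered, 14070 had 1 symbol. Each gene was represented by its brightest probe, which gave 9168 genes tested. Arrays give no counts, and the number of arrays limits the precision.

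One limma model (version 3.58.1 in R 4.3.3, lmFit and eBayes) with 7 groups was fitted to all 24 arrays. The contrasts were FcMR against isotype at 4, 18 and 48 h, the mean of these 3 effects, their difference between times, and isotype at 4, 18 and 48 h against 0 h. The moderated F test of limma gave the genes that responded at any time and the genes whose response differed between times. Probabilities were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and all tests were two-sided. Where a group had no array above background, the fold against the background level is given as a lower bound, written "at least". Where only some arrays of a group were above background, their number limits the fold.

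Gene lists were fixed before the data were examined: 21 programs of activation, inhibition, cytokines, interferon response, metabolism, stress, cell cycle and migration, and 6 lists of markers of other cell types. They hold 532 members, of which 494 have a named probe. The 23 lists with at least 5 tested genes were tested with camera of limma, at a preset inter-gene correlation of 0.01 and beside it with an estimated correlation, and adjusted over the 23 lists. The other 4 lists (NK cell, CD4 T cell, erythroid and platelet markers) are given as counts. Counts of list members are given over all genes tested and, beside that, adjusted over the list alone.

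Genes were named by a rule fixed before the data were examined. For each FcMR contrast, the 8 genes with the largest rise and the 8 with the largest fall were named among those past the threshold whose 3 arrays per group did not overlap. For the mean effect, the group means had to differ in the same direction at all 3 times. With fewer than 3 such genes, the 3 with the smallest p were named as not passing. For isotype against 0 h the rule took 6 and 6. For each list, up to 4 members past the threshold were named by size of effect, or up to 2 by smallest p. Ctla4, Ptprc (CD45), Mrc1 (the mannose receptor), Bcl6, Il2, Ifng, Gzmb and Cd8a were given throughout. Genes with provisional symbols were passed over.

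The model was tested on simulated data with 200 changed genes. At 18 h it called 40.3% of genes changed by a log2 value of 0.5 and 88.1% of those changed by 1, with 4 false calls. The simulated noise was independent and had the same spread in every group. It held no array that lies with another group, so these shares do not carry over to the real 18 h arrays. Alternatives were: no filter and a stricter filter at 6 SDs; every probe on its own, or the mean of a gene's probes; trend and robust eBayes; array quality weights; only the arrays compared; the replicate number as a block; a 2-fold threshold; and each array left out in turn. A normexp background correction, the stricter filter at 6 SDs, centring of each array on the median of its tested genes, and leaving out a pair of arrays that stood apart from their groups were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.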

Results

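RNA was profiled in sorted CD8+ T cells from DesTCR mice before culture (0 h, 6 arrays) and after 4, 18 and 48 h with dendritic cells lacking the mannose receptor, in the presence of FcMR or an isotype control (3 arrays per group and time). The title of the series names T cell tolerance, CD45 (Ptprc) and CTLA-4 (Ctla4), so these genes are given at every time. The first principal component held 48% of the variance and the second held 17.4%. Of 24 arrays, 2 isotype arrays lay closest to an array outside their own group and are called below the arrays that stood apart. The 18 h FcMR arrays 1 and 3 also lay closest to an array outside their group, in each case 18 h isotype array 3 (r = 0.992 and 0.995). The 18 h isotype array 3 correlated most closely with an 18 h FcMR array (r = 0.995 across genes, which are not independent replicates, against 0.960 with its own group). The 48 h isotype array 1 correlated most closely with an 18 h isotype array (r = 0.942, against 0.906 with its own group). Both kept their labels, and values without them are given where they change a result.

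**Figure D1:**
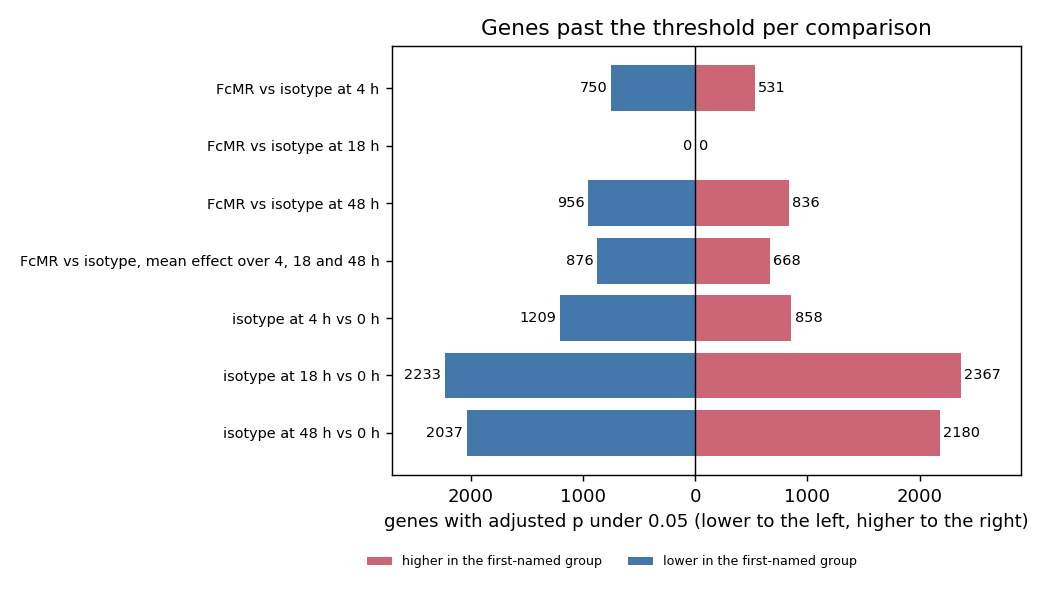
Number of genes past an adjusted p of 0.05 in each comparison (limma, 9168 genes tested), higher in the first-named group to the right and lower to the left. FcMR against isotype gave 1281 genes at 4 h, 0 at 18 h and 1792 at 48 h, and isotype against 0 h gave 2067, 4600 and 4217 genes at 4, 18 and 48 h.

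The comparison of FcMR with isotype at 4 h asks what the fusion protein changed early in the culture. Most of the largest rises were interferon-stimulated genes. Rsad2, an antiviral enzyme, was at 12.08 ± 0.31 with FcMR and 7.70 ± 0.21 with isotype (log2, SD, n = 3 each), a 20.9-fold rise (SE of the log2 difference 0.15, adjusted p = 2.65e-14). Usp18, a brake on interferon receptor signalling, rose 14.1-fold (SE 0.59), Eif2ak2, the RNA-sensing kinase PKR, 13.8-fold (SE 0.20), and Isg20, an antiviral exonuclease, by 3.58 on the log2 scale (SE 0.12). Mx2 and Dhx58, both antiviral, rose by 3.57 and 3.41 on the log2 scale, as did Rgs1, a regulator of chemokine receptor signalling (3.38), and the chemokine Cxcl10 (3.29). The largest falls were Fam78a (6.25-fold lower, SE 0.24), the stress-response gene Sesn1 (log2 difference -1.97, SE 0.28), the T cell chemokine Xcl1 (-1.92, SE 0.47), Rassf2 (-1.92), Golm1 (-1.89), the cannabinoid receptor Cnr2 (-1.87), Bambi-ps1 (-1.69) and the chemoattractant Il16 (-1.67). In all, 1281 genes passed, 531 higher and 750 lower with FcMR, and with array quality weights 2213 passed. Over 2-fold the balance was the other way, with 191 higher and 132 lower. Without 4 h FcMR array 2, 1006 genes passed, 489 higher and 517 lower, and 865 of them were shared in direction with the 1281. The 3 arrays of each group did not overlap for 29.5% of genes, against 10% by chance.

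Ifng, the main effector cytokine of CD8+ T cells, was 3.49-fold higher with FcMR at 4 h (SE 0.48, adjusted p = 0.0139), although without 4 h isotype array 3 the adjusted p was 0.0691. Bcl6, a transcriptional repressor, was 2.41-fold lower (log2 difference -1.27, SE 0.22, adjusted p = 0.000398). Ctla4 was at 7.77 ± 0.23 and 7.61 ± 0.12 (adjusted p = 0.875), and Ptprc differed by 0.31 (adjusted p = 0.469). Il2 differed by 0.35 (adjusted p = 0.684), and Gzmb, encoding granzyme B, was near background on all arrays at this time.

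Of 20 tested type I interferon response genes, 19 rose at 4 h and 0 fell (19 also adjusted over the list alone). Their mean per array was 11.09 ± 0.07 with FcMR, 8.77 ± 0.24 with isotype and 8.68 ± 0.12 at 0 h (camera adjusted p = 8.75e-40, and adjusted p = 0.000629 with an estimated correlation). The interferon gamma response and antigen processing list had 10 of 16 genes up (11 adjusted over the list alone), among them Gbp2 (1.64), Nlrc5, the activator of class I genes (1.40), and the immunoproteasome subunit Psmb10 (1.38), with an adjusted p = 3.95e-11, or 0.0110 with an estimated correlation. Among 17 interleukin 2 receptor and STAT5 response genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone). They included the cytokines Osm (3.06) and Lif (3.05), the receptor chain Il2ra (1.79) and the feedback inhibitor Cish (1.30), with an adjusted p = 4.23e-07, or 0.000438 with an estimated correlation. Effector and tolerance transcription factors had 6 genes up and 1 down of 17 (7 and 2 adjusted over the list alone), with Batf at 1.73, Bhlhe40 at 1.44 and Irf8 at 1.31. Their adjusted p was 0.00829, or 0.0241 with an estimated correlation, and the latter was 0.0591 without 4 h isotype array 1.

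Dendritic cell and myeloid markers also moved at 4 h. Of 18 tested, 3 rose and 0 fell (3 adjusted over the list alone): the cytokine Il1b (2.15), the co-stimulatory ligand Cd86 (1.04) and the Fc receptor chain Fcer1g (0.32). Their mean was 8.60 ± 0.04 with FcMR, 8.30 ± 0.08 with isotype and 7.43 ± 0.06 at 0 h (adjusted p = 0.00843, but adjusted p = 0.287 with an estimated correlation, and 0.0552 without 4 h isotype array 1). B cell markers had 0 of 5 genes past the threshold, erythroid markers 0 of 1 and platelet markers 0 of 2. Of 3 tested CD4 T cell markers, 1 rose, Tnfsf8 (at least 1.40-fold), and no NK cell marker was above background on enough arrays to be tested.

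Immediate early activation genes had 7 of 22 members up at 4 h (8 adjusted over the list alone), including the transcription factors Jun (1.49), Atf3 (1.36), Myc (1.24) and Irf4 (1.23), with an adjusted p = 0.000212, but adjusted p = 0.280 with an estimated correlation. Ribosome biogenesis had 3 of 22 genes up (3 adjusted over the list alone): Wdr43 (1.19), Nop58 (1.15) and Nop2 (0.77). Its adjusted p was 0.00227, but adjusted p = 0.543 with an estimated correlation and 0.165 without 4 h FcMR array 2. Among 18 naive and quiescence genes 0 rose and 5 fell (1 and 7 adjusted over the list alone), such as the signalling inhibitor Pik3ip1 (-1.10), the transcription factors Klf3 (-0.70) and Lef1 (-0.64), with an adjusted p = 0.0387, but adjusted p = 0.543 with an estimated correlation and 0.546 without 4 h FcMR array 2. Cytotoxic effector genes (3 of 12 up, Tnfsf10 at 1.11, Klrk1 at 1.05 and Srgn at 0.65; 3 adjusted over the list alone) had an adjusted p = 0.0377, but adjusted p = 0.389 with an estimated correlation and 0.129 without 4 h FcMR array 3. Cytokines and chemokines had 3 up and 2 down of 17 (the same counts adjusted over the list alone; adjusted p = 0.0381, but adjusted p = 0.395 with an estimated correlation and 0.0578 without 4 h isotype array 3). Apoptosis regulators had 3 up and 1 down of 16, also adjusted over the list alone, with the initiator caspase Casp8 at 2.21 and the death receptor Fas at 1.44 (adjusted p = 0.0325, but adjusted p = 0.240 with an estimated correlation and 0.0601 without 4 h isotype array 1).

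Co-inhibitory receptors and ligands moved both ways at 4 h. Of 10 tested, Lag3 (2.30-fold), Cd274, encoding PD-L1 (log2 difference 1.11), and Btla (0.81) rose and Cd160 (-1.31) fell (adjusted p = 0.286 for the list). Of 14 co-stimulatory genes, 2 rose and 2 fell, with Slamf1 at 1.09, Cd27 at -1.02 and Cd28 at -0.77. Anergy genes had 2 up and 2 down of 14, among them the diacylglycerol kinase Dgkz (-0.90) and Egr2 (0.53). Proximal T cell receptor signalling genes had 2 up and 3 down of 20, with Cd3g at -1.02, Lat at -0.79 and Prkcq at 0.66. Adjusted over the list alone, these counts were 3 and 1, 2 and 4, 2 and 3, and 2 and 6. Glycolysis had 3 of 16 genes up (3 adjusted over the list alone; Hk1 at 0.79), and migration receptors 2 up and 1 down of 17 (2 and 2 adjusted over the list alone; Itgb7 at -1.09, Cxcr5 at 0.89). The unfolded protein list had 1 up and 1 down of 24 (0 and 1 adjusted over the list alone; Herpud1 at -1.04), and cholesterol synthesis 1 up of 13 (0 adjusted over the list alone; Insig1 at 0.69). None of 23 S phase, 13 G2 and M phase or 11 heat shock genes passed in limma, while 2323 of all genes had an unadjusted p under 0.05. Calls of some list members ended with 1 array left out. Their highest adjusted p was 0.229 for Lat, 0.223 for Nop2, 0.215 for Itgb7, 0.194 for Egr2, 0.104 for Cd3g, 0.0929 for Btla and 0.0757 for Slamf1, each without 4 h FcMR array 2. It was 0.207 for Prkcq and 0.0754 for Fcer1g without FcMR array 1, and 0.107 for Jun and 0.0737 for Klrk1 without FcMR array 3. Without isotype array 1 it was 0.182 for Insig1 and 0.0523 for Srgn, without isotype array 2 0.0578 for Fas, and without isotype array 3 0.0553 for Nlrc5. Golm1 had a log2 difference of -1.28 without 4 h FcMR array 2, and had an adjusted p = 0.0890 with only the 6 arrays compared. With the mean of a gene's probes the log2 difference was 1.86 for Cxcl10 and -0.91 for Il16, and with normexp background correction it was 4.29 for Mx2. With isotype Mx2 was above background on 1 of 3 arrays, and Lag3 and Il1b on 2 of 3.

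At 18 h the same comparison gave no gene past the threshold. In limma 0 of 9168 genes passed and 1534 had an unadjusted p under 0.05, with a smallest adjusted p of 0.0771 and non-overlapping arrays for 19% of genes, against 10% by chance. The inhibitory receptor Ctla4 was at 10.87 ± 0.26 with FcMR and 9.41 ± 1.19 with isotype (n = 3 each), a log2 difference of 1.46 that did not pass (SE 0.38, adjusted p = 0.0771). Its isotype arrays were at 8.77, 8.68 and, for array 3, 10.78. Also not passing, each with an adjusted p of 0.0771, were Acad8 (0.50, above background on 1 of 3 isotype arrays), Ap2s1 (0.78) and Exoc4 (0.69), and in the other direction the glutathione-degrading enzyme Chac1 (-1.98), Tomm40l (-0.92) and Lrmp (-1.43). Values for the remaining genes of interest were 0.15 for Ptprc (adjusted p = 0.828), -0.07 for Bcl6 (0.923), 0.52 for Il2 (0.578) and -1.35 for Ifng (0.151).

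Without 18 h isotype array 3, which leaves 2 isotype arrays, 1379 genes passed at 18 h, 721 higher and 658 lower with FcMR. Array quality weights, 0.248 for this array, gave 2627 genes with the balance the other way (1254 higher and 1373 lower), and 974 were higher and 979 lower without both arrays that stood apart, a setting chosen after seeing the data. Leaving out any other 18 h array gave 0 genes. Isotype array 3 was singled out after it was seen to lie with the FcMR arrays. Leaving it out therefore widens the differences and narrows the isotype spread by construction. Adjusted p-values for FcMR at 18 h without it, here and below, are not independent evidence of an effect. With 18 h isotype array 3 alone left out, Ctla4 was 4.43-fold higher (log2 difference 2.15, SE 0.25, adjusted p = 8.71e-06). By the rule for naming genes, the largest rises were Crip2 (3.40), the tetraspanin Cd81 (3.01), the gap junction gene Gja1 (2.95), the mitochondrial ribosome gene Mrps31 (2.75), the oxygen-sensing hydroxylase Egln3 (2.46, with 1.73 in all arrays), Acot1 (at least 4.05-fold), Csrnp2 (2.32) and Phlda3 (2.28). The largest falls were the chemokine Xcl1 (-2.78, with -2.00 in all arrays), Chac1 (-2.74), the T cell adhesion receptor Crtam (-2.58), Pacsin1 (-2.06), the glycine transporter Slc6a9 (-2.06), Ifng (3.82-fold, log2 difference -1.93, adjusted p = 0.00706), the chemokine Ccl9 (-1.93) and Lrmp (-1.92). Gja1 was above background on 1 of the 2 isotype arrays and Crtam on 1 of 3 FcMR arrays. Ptprc (0.04), Il2 (0.80) and Bcl6 (-0.03) did not pass, and Gzmb was near background on all of these arrays.

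**Figure D2:**
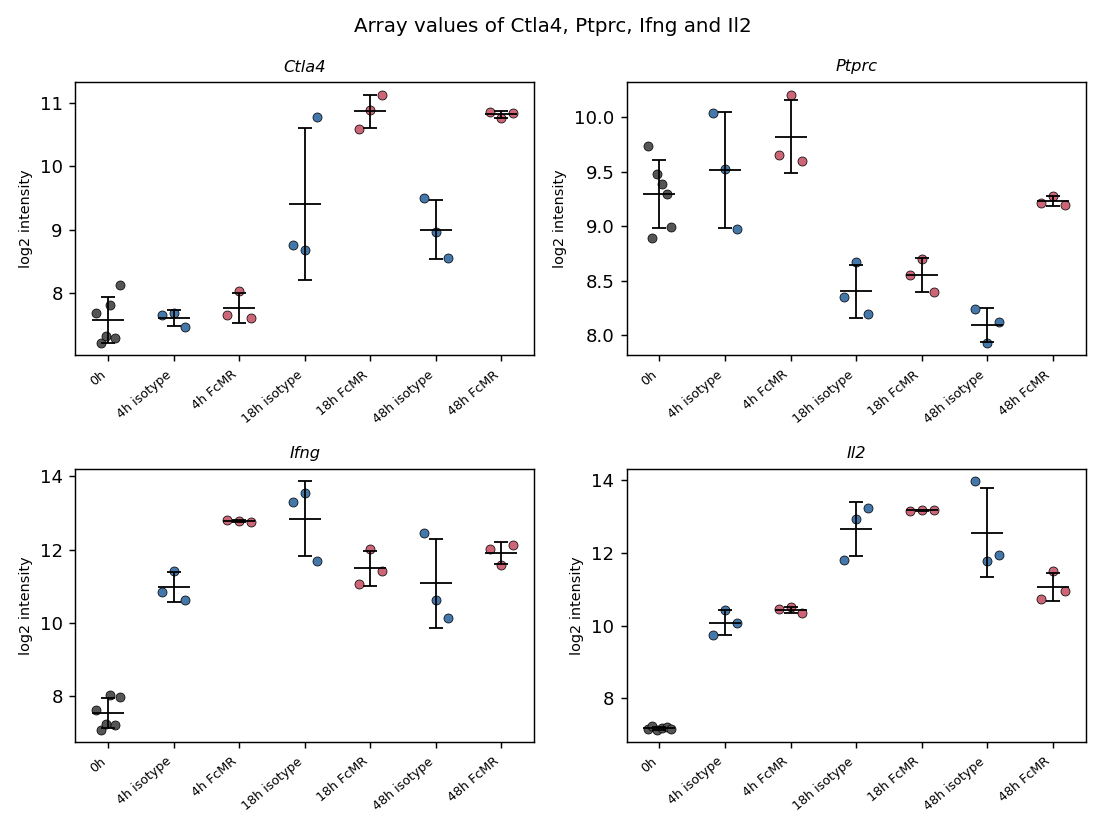
Log2 intensity of Ctla4, Ptprc, Ifng and Il2 on each array (dots) at 0 h (grey) and at 4, 18 and 48 h with isotype (blue) or FcMR (red), with black bars for the group mean ± SD. At 18 h, Ctla4 on isotype array 3 (10.78) lies among the FcMR arrays (10.60, 10.89 and 11.12) and not beside the other isotype arrays (8.77 and 8.68).

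Among the lists at 18 h, glycolysis genes were higher with FcMR as a set (adjusted p = 1.30e-07, but adjusted p = 0.232 with an estimated correlation). Of 16 tested, 0 passed over all genes and 9 rose adjusted over the list alone, with Egln3 at 1.73 and the phosphofructokinase Pfkp at 0.75. Without isotype array 3, 9 rose and 0 fell (adjusted p = 2.93e-07, but adjusted p = 0.115 with an estimated correlation). Unfolded protein and amino acid stress genes were lower as a set (24 tested, 0 past the threshold, 1 up and 6 down adjusted over the list alone, Trib3 at -1.36; adjusted p = 0.000648, but adjusted p = 0.232 with an estimated correlation), and without array 3, 1 rose and 7 fell. S phase genes were lower as a set (23 tested, 0 past the threshold and 0 adjusted over the list alone; adjusted p = 0.000312, but adjusted p = 0.811 with an estimated correlation), and 7 fell without array 3. Migration receptors were higher as a set (17 tested, 3 up adjusted over the list alone; adjusted p = 0.00409, but adjusted p = 0.265 with an estimated correlation), and 4 rose without array 3. Cytokines (2 of 17 down adjusted over the list alone), ribosome biogenesis (0 of 22), cholesterol synthesis (0 of 13) and heat shock genes (1 of 11) were lower as sets, with adjusted p between 0.0344 and 0.0439, but adjusted p = 0.811 for each with an estimated correlation. Without 18 h isotype array 2 the adjusted p was 0.193 for cytokines, 0.254 for ribosome biogenesis and 0.110 for heat shock genes, and without isotype array 1 it was 0.271 for cholesterol synthesis. The other 15 lists had adjusted p of at least 0.177. On S phase genes the isotype arrays had means of 8.96, 9.10 and, for array 3, 8.21, beside 8.15 to 8.23 with FcMR.

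At 48 h the comparison asks which changes mark the cells after longer culture with FcMR. The enzyme transglutaminase 2, Tgm2, was at 11.52 ± 0.41 with FcMR and 7.96 ± 0.75 with isotype (log2, SD, n = 3 each), an 11.8-fold rise (SE 0.24, adjusted p = 6.41e-09). Egln3, an oxygen-sensing hydroxylase, rose 9.43-fold (SE 0.38), followed by the glycogen regulator Ppp1r3b (log2 difference 2.79), the glycolytic enolase Eno2 (2.75), the stress and differentiation gene Ndrg1 (2.66), Ier3 (2.58), the mitochondrial Mgarp (2.42) and Dennd11 (2.36). The chemokine Xcl1 showed the largest fall, 11.6-fold (log2 difference -3.54, SE 0.47), followed by the inhibitory receptor Cd160 (-2.41, SE 0.19), Osr2 (at least 4.96-fold lower), the centromere histone Cenpa (-2.25), the chemokine Ccl3 (-2.23), Glipr1 (-2.12), Phlda1 (-1.95) and the mitotic gene Gtse1 (-1.90). The place of Osr2 in this order is open, since its fall is a lower bound. In all, 1792 genes passed, 836 higher and 956 lower. The balance was the other way with each array centred on the median of its tested genes (1016 higher and 759 lower), with every probe on its own (1565 and 1312), over 2-fold (199 and 142), with only the 6 arrays of this time (308 and 264) and without 48 h FcMR array 1 (621 and 582). The centring, which moved each array by at most 0.055, was chosen after seeing the data. The arrays of the groups did not overlap for 31.3% of genes, against 10% by chance.

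Both genes of the title were higher with FcMR at 48 h. Ctla4 was at 10.82 ± 0.05 with FcMR and 9.01 ± 0.47 with isotype, a 3.52-fold rise (SE 0.38, adjusted p = 0.00186). Ptprc was at 9.23 ± 0.04 and 8.09 ± 0.16, a 2.19-fold rise (SE 0.23, adjusted p = 0.00145). This value rests on the brightest of 3 Ptprc probes: the others differed by 0.19 (adjusted p = 0.313) and -0.04 (adjusted p = 0.940), and the mean of the probes by 0.43. Il2 was 2.83-fold lower (log2 difference -1.50, adjusted p = 0.0111), but the difference was -0.79 without 48 h isotype array 1, and the adjusted p was 0.0567 without 48 h FcMR array 1 and 0.0614 with the replicate number as a block. Bcl6 was 1.66-fold lower (log2 difference -0.73, adjusted p = 0.0250), a call that ended without any 1 of isotype array 2 (0.0550), isotype array 3 (0.147), FcMR array 1 (0.103) or FcMR array 3 (0.0698). Ifng differed by 0.83 (adjusted p = 0.251), and by 1.52 without isotype array 1 (adjusted p = 0.0110). Gzmb differed by -0.18 (adjusted p = 0.221). With FcMR, Bcl6 and Gzmb were each above background on 1 of 3 arrays.

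Glycolysis genes rose together at 48 h. Of 16 tested, 11 rose and 0 fell (14 adjusted over the list alone), among them the glucose transporters Slc2a3 (2.33) and Slc2a1 (1.53) and the phosphofructokinase Pfkp (2.27). The adjusted p was 2.37e-12, or 0.0408 with an estimated correlation. Without 48 h isotype array 1, 11 rose and 0 fell, but with adjusted p = 0.0784 with an estimated correlation, which was also 0.0673 without isotype array 3 and 0.0515 without FcMR array 2. Slc2a3 was at 2.93 without isotype array 2. Among 17 interleukin 2 receptor and STAT5 response genes, 13 rose and 0 fell (13 and 1 adjusted over the list alone), including the kinase Jak3 (2.25), the feedback inhibitor Socs3 (2.09), the cytokine Lif (2.07) and Stat5a (1.52), with an adjusted p = 1.89e-08, or 0.000125 with an estimated correlation. Proximal T cell receptor signalling genes had 7 of 20 members up and 0 down (7 adjusted over the list alone), including the signalling chain Cd247 (1.02), the phosphatase Ptpn6 (1.01) and the kinase Csk (0.85). Their adjusted p was 0.000388, but adjusted p = 0.0680 with an estimated correlation, and 0.0510 without isotype array 1. Effector and tolerance transcription factors had 5 up and 1 down of 17 (5 and 2 adjusted over the list alone), with Hif1a at 1.43 and Id2 at 1.06 (adjusted p = 0.0345, but adjusted p = 0.0776 with an estimated correlation).

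G2 and M phase genes were lower with FcMR at 48 h, to an extent that depended on isotype array 1. They had 10 of 13 members down and 0 up (11 adjusted over the list alone), including Cenpa, the anaphase activator Cdc20 (-1.89), Prc1 (-1.57) and Kif23 (-1.48), with an adjusted p = 2.21e-05, but adjusted p = 0.608 with an estimated correlation. S phase genes had 3 of 23 down (3 adjusted over the list alone): Tyms (-1.69; -1.06 without isotype array 1), Rrm2 (at least 2.43-fold lower, but at least 1.30-fold without isotype array 1) and Tk1 (at least 2.23-fold lower, but at least 1.15-fold without isotype array 1). The adjusted p of the list was 0.000757, but adjusted p = 0.644 with an estimated correlation. The isotype arrays 1, 2 and 3 had means of 10.21, 8.12 and 7.57 for G2 and M phase and 10.21, 8.16 and 7.83 for S phase, beside 7.31 to 7.36 with FcMR for G2 and M phase and 7.93 to 7.97 with FcMR for S phase, which lies above isotype array 3. Without isotype array 1, 7 G2 and M phase genes fell (median -0.45, with -1.33 in all arrays; adjusted p = 0.00334, but adjusted p = 0.498 with an estimated correlation). Cdc20 was then at -1.001, Kif23 at -0.81 and Prc1 at -0.52. Of the S phase genes 1 rose and 3 fell without it (median -0.07, adjusted p = 0.857). Calls of Prc1 (adjusted p = 0.0743) without FcMR array 2 and of Tk1 (0.0927) and Rrm2 (0.0622) without FcMR array 1 ended. The same array had the lowest type I interferon mean, 7.52 against 8.29 and 8.48 on the other isotype arrays. Type I interferon genes had 5 of 20 up and 0 down (5 adjusted over the list alone; Dhx58 at 1.01, Isg15 at 0.89; adjusted p = 0.05003), but without isotype array 1 2 rose and 1 fell (median -0.02, adjusted p = 0.772) and Isg15 was at 0.41 (adjusted p = 0.133). With another single array of this time left out the adjusted p of the list was as low as 0.00197 (without isotype array 3), but with adjusted p = 0.398 with an estimated correlation, and without FcMR array 1 or 3 only 2 genes rose. Dhx58 did not pass without FcMR array 1 (adjusted p = 0.0528). The interferon gamma list had 3 of 16 up (3 adjusted over the list alone; Psmb8 at 1.22; adjusted p = 0.0733).

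**Figure D3:**
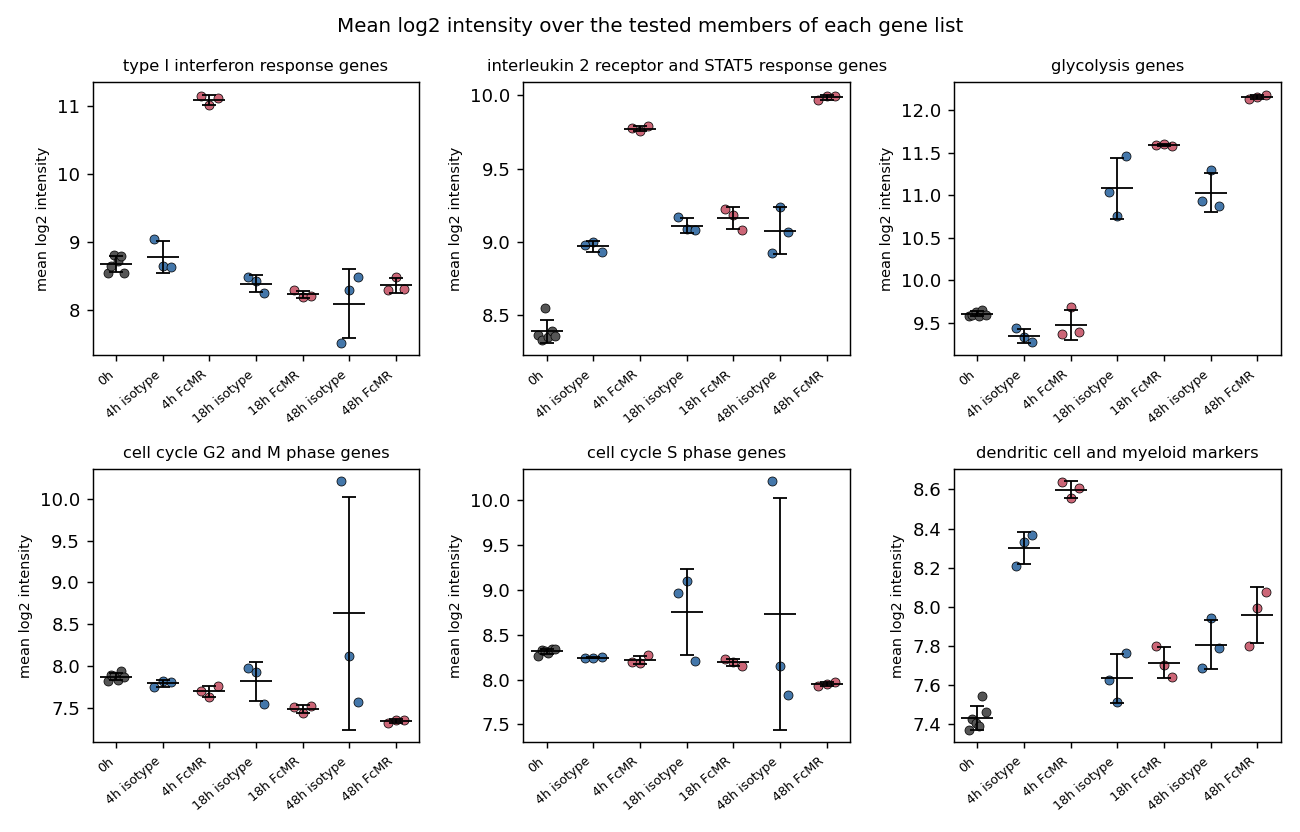
Mean log2 intensity of 6 gene lists on each array (dots), by time and treatment. Type I interferon genes are at 11.09 with FcMR and 8.77 with isotype at 4 h, glycolysis genes are at 12.16 and 11.03 at 48 h, and 48 h isotype array 1 lies at 10.21 for G2 and M phase genes, above the other isotype arrays (8.12 and 7.57).

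Cytokines and chemokines moved both ways at 48 h, with 7 up and 4 down of 17 (8 and 5 adjusted over the list alone), Tnf at 1.67 beside the falls of Xcl1 and Ccl3. Their median difference was 0.44 and their mean -0.01 (adjusted p = 0.131). Co-inhibitory receptors had 3 up and 4 down of 10 (3 and 5 adjusted over the list alone), with Btla at -1.18 and Cd96 at -0.97 beside Cd160 and Ctla4. Co-stimulatory genes had 2 up and 3 down of 14, also adjusted over the list alone, with Tnfrsf9, encoding 4-1BB, at 1.06 and Cd70 at -1.72. Anergy genes had 1 up and 4 down of 14, also adjusted over the list alone, including the falls of Egr3 (-1.72), Egr2 (-1.35) and Tle4 (-1.24). Immediate early genes had 4 up and 5 down of 22 (4 and 6 adjusted over the list alone), with Egr1 at -1.37. Naive and quiescence genes had 5 of 18 up (5 adjusted over the list alone; Igfbp4 at 1.87, Foxo1 at 1.07; adjusted p = 0.0521). Migration receptors had 6 up and 1 down of 17, also adjusted over the list alone, with Cxcr4 at 1.53 and Gpr183 at 1.31 (adjusted p = 0.0345, but adjusted p = 0.455 with an estimated correlation, 0.134 without isotype array 1 and 0.0635 without FcMR array 2). Apoptosis regulators had 4 up and 1 down of 16 (5 and 2 adjusted over the list alone; Bcl2 at 1.26), and the unfolded protein list 3 up and 2 down of 24 (Calr at 1.61, Atf4 at -0.74). Cytotoxic effector genes had 1 up and 1 down of 12 (Srgn at 1.23, Fasl at -0.61). Ribosome biogenesis (3 of 22, Nop58 at -0.87), cholesterol synthesis (3 of 13, Hsd17b7 at -0.50) and heat shock (1 of 11, Hspe1 at -0.78) had falls and 0 rises. Myeloid markers had 5 of 18 up and 0 down (5 adjusted over the list alone; Il1b at 1.44, Fscn1 at 0.81; adjusted p = 0.0570), B cell markers 1 of 5 up (Fcmr at 0.43), and CD4 T cell, erythroid and platelet markers 0.

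Some of these counts rested on isotype array 1. Without it, apoptosis regulators had 2 up and 4 down, cholesterol synthesis 4 up and 2 down, ribosome biogenesis 1 up and 1 down, heat shock 1 up and 1 down, cytotoxic genes 1 up and 4 down, immediate early genes 2 up and 6 down, naive genes 5 up and 1 down, migration receptors 4 up and 0 down, myeloid markers 3 up and 1 down, and B cell markers 0. Calr was at 2.45 without it, and Bcl2 (0.54, adjusted p = 0.249) and Hsd17b7 (-0.23, adjusted p = 0.217) did not pass. Other calls ended without a single array: Calr (adjusted p = 0.0828) and Cd96 (0.0637) without isotype array 2, Atf4 (0.129) without isotype array 3, Nop58 (0.101) and Hspe1 (0.0796) without FcMR array 2, and Fcmr (0.184) without FcMR array 3. Prc1 and Kif23 were above background on 1 of 3 FcMR arrays and Fasl on 2 of 3, and with isotype Il1b and Fcmr were above it on 1 of 3 arrays and Cxcr4 and Fscn1 on 2 of 3.

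Leaving out 48 h isotype array 1 gave 2188 genes, 1427 of them shared in direction with the 1792, and changed the log2 difference to 2.02 for Eno2, 1.71 for Mgarp (3.13 without isotype array 2), -1.59 for Cenpa and -1.51 for Ccl3. By the rule for naming genes the largest rise was then Hnrnpl, an RNA splicing factor, at 12.16 ± 0.27 with FcMR (n = 3) and 7.27 ± 0.05 with isotype (n = 2), with 1 of the 2 isotype arrays above background (log2 difference 4.90 in limma, SE 0.46, adjusted p = 4.25e-07, with 3.17 in all arrays). Tgm2 (3.30), Egln3 (3.18), the metallothionein Mt1 (2.66), Calr, Dennd11 (2.41), Pfkp (2.38) and P4ha2 (2.32) followed. The largest falls were Xcl1 (-2.98), Osr2 (at least 6.86-fold), Glipr1 (-2.70), Zfp365 (-2.45), Crip2 (-2.45), Cd160 (-2.41), Phlda1 (-2.36) and Acot1 (-2.24). With only the 6 arrays of this time in the model 572 genes passed, and Eno2 (adjusted p = 0.0539), Mgarp (0.0911), Cenpa (0.0819), Ccl3 (0.0867), Glipr1 (0.0705), Bcl6 (0.213) and Il2 (0.206) did not. The mean of a gene's probes gave log2 differences of 1.83 for Egln3 and 1.88 for Ppp1r3b.

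Averaged over the 3 times, 1544 genes responded to FcMR, 668 higher and 876 lower. The balance was the other way with each array centred on the median of its tested genes (807 higher and 632 lower), with every probe on its own (1269 and 1174) and over 2-fold (39 and 7). The rises were led by Ppp1r3b (3.84-fold, SE 0.24, adjusted p = 1.19e-05), the cytokine Lif (3.64-fold, SE 0.13), Egln3 (3.37-fold), Tgm2 (2.97-fold), Il1b (log2 difference 1.47), Usp18 (1.43), Eno2 (1.38) and the guanylate-binding protein Gbp5 (1.34). Xcl1 had the largest fall (5.60-fold, SE 0.27, adjusted p = 3.01e-06), followed by Cd160 (-1.34), Cenpa (-1.22), Golm1 (-1.16), Mmd (-1.12), the transporter Slco4a1 (-1.09), Crtam (-0.998) and Ipcef1 (-0.92). Ctla4 was 2.21-fold higher (SE 0.22, adjusted p = 0.00106), Ptprc 1.44-fold higher (SE 0.13, adjusted p = 0.00873) and Bcl6 1.62-fold lower (SE 0.13, adjusted p = 0.000878). The Ptprc value rests on the brightest of 3 probes, and the others differed by 0.14 (adjusted p = 0.201) and 0.06 (adjusted p = 0.786). Il2 (-0.21, adjusted p = 0.585), Ifng (0.43, adjusted p = 0.325) and Gzmb (-0.07, adjusted p = 0.435) did not pass. With the mean of a gene's probes the averaged difference was 1.83-fold for Egln3 and 2.30-fold for Ppp1r3b. With array quality weights 2997 genes passed, and 2516 did without both arrays that stood apart, a setting chosen after seeing the data.

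In the averaged effect 8 of 17 interleukin 2 receptor and STAT5 response genes rose and 0 fell (11 adjusted over the list alone; adjusted p = 3.41e-11, or 2.13e-05 with an estimated correlation). Type I interferon genes had 16 of 20 up (18 adjusted over the list alone), the interferon gamma list 8 of 16 (8 adjusted over the list alone) and glycolysis 11 of 16 (14 adjusted over the list alone), with 0 down in each and adjusted p of 0.00904, 0.0280 and 0.0175 with an estimated correlation. That of the interferon gamma list was 0.0707 without 18 h isotype array 3. Effector and tolerance transcription factors had 8 up and 2 down of 17, also adjusted over the list alone (adjusted p = 0.00202, or 0.0152 with an estimated correlation). Dendritic cell and myeloid markers had 6 of 18 up and 0 down (adjusted p = 0.00144, but adjusted p = 0.189 with an estimated correlation). S phase (4 of 23 down, adjusted p = 0.000653) and G2 and M phase genes (3 of 13 down, adjusted p = 0.00106) were lower as sets, but each with adjusted p = 0.591 with an estimated correlation. Without 48 h isotype array 1 their medians were -0.17 and -0.23 (-0.47 for each in all arrays), with 7 and 8 down. Migration receptors (4 of 17 up), proximal T cell receptor signalling (4 up and 1 down of 20), immediate early genes (5 up and 3 down of 22) and apoptosis regulators (2 of 16 up) were higher as sets, with adjusted p of 0.0181, 0.0465, 0.0465 and 0.0424, but adjusted p = 0.245, 0.281, 0.591 and 0.226 with an estimated correlation. Without 48 h isotype array 1 these lists had adjusted p of 0.0628, 0.307, 0.187 and 0.128, with 4 up and 1 down for migration receptors, 4 up and 3 down for proximal signalling and 4 up and 2 down for apoptosis regulators. The last list had 4 up and 1 down without 18 h isotype array 3, and proximal signalling then had an adjusted p = 0.101.

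A joint test of the 3 times gave 2763 genes that responded to FcMR at any time, and 1912 genes had a response that differed between times. Array quality weights gave 5039 and 3926 genes, the replicate number as a block gave 1248 genes that differed, and without both arrays that stood apart the counts were 4379 and 3451. Pairwise, 694 genes differed between 18 and 4 h, 1455 between 48 and 4 h and 1020 between 48 and 18 h. Of the genes called at both 4 and 48 h, 112 rose at both times, against 48.4 expected if the calls were independent, and 97 fell at both (78.2 expected). Another 45 rose at 4 h and fell at 48 h (55.4 expected), and 82 fell and then rose (68.4 expected). For Ctla4 and Ptprc the difference between times did not pass (adjusted p = 0.0601 and 0.0602). The probes of the mannose receptor gene, Mrc1, and of Cd8a were above background on 0 of 24 arrays. Since the cells were sorted as CD8+, absence of Cd8a RNA cannot be read from these values. Mrc1 RNA was not detected on any array, and the dendritic cells of the cultures lack the mannose receptor. Whether the Mrc1 probe can detect its RNA was not tested.

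Isotype against 0 h at 4 h shows the course of the cells in culture without the fusion protein. Chemokines and activation factors rose: Ccl4 37.7-fold (SE 0.42, n = 3 and 6, adjusted p = 1.25e-08), the transcription factor Irf4 26.8-fold (SE 0.15), Xcl1 19.7-fold, Ccl3 18.9-fold, Egr3 17.3-fold and Tnf 16.2-fold. Some of the genes set against 0 h were above background on only part of the 6 arrays at 0 h, which limits their folds at every time: Irf4 and Il2ra on 1, Ccl3, Cd83 and Cd200 on 2, Ifng, Bhlhe40 and Cd74 on 3, Tnf, Ctla4, Tnfrsf9 and Birc5 on 4, and Irf8 and Asns on 5. The largest falls were Ly6c1 (log2 difference -2.72), the mTOR inhibitor Ddit4 (-2.66), Dtx1 (-2.24), Slc16a5 (-2.23), Nkg7 (-2.05) and Ly9 (-1.85). Il2 rose at least 6.88-fold, Ifng by 3.44 on the log2 scale and Bcl6 by 1.99 (adjusted p = 2.19e-07), while Ctla4 (0.03) and Ptprc (0.22) did not pass and Gzmb was near background on all arrays, as it was at 18 h. Of 2067 genes past the threshold 858 were higher and 1209 lower, while over 2-fold 198 were higher and 113 lower. Immediate early genes had 16 of 22 up and 0 down (16 adjusted over the list alone; Egr2 at 3.64, Nfkbid at 3.13; adjusted p = 7.62e-15, or 0.00800 with an estimated correlation). Cytokines and chemokines had 10 of 17 up and 0 down (10 adjusted over the list alone; adjusted p = 0.00708 with an estimated correlation). Co-stimulatory genes had 5 up and 1 down of 14, also adjusted over the list alone, with Tnfsf14 at 2.88 and Tnfrsf9 at 1.88 (adjusted p = 0.00441, or 0.0125 with an estimated correlation).

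Dendritic cell and myeloid markers rose along with these groups, 11 of 18 up and 0 down (11 adjusted over the list alone), with Lyz1 (lysozyme) at least 8.23-fold, Cd83 at 2.81, the class II chain Cd74 at 1.75 and Ccl17 at least 2.53-fold (adjusted p = 5.57e-09, or 0.00800 with an estimated correlation). Interleukin 2 receptor and STAT5 response genes had 8 up and 1 down of 17, with Cish at 3.31, and effector and tolerance transcription factors 6 up and 1 down of 17, with Irf8 at 3.17 (adjusted p = 0.00522 and 0.00708 with an estimated correlation). The anergy list (6 up and 1 down of 14, adjusted p = 0.00486), the interferon gamma list (8 up and 3 down of 16, 0.0101), ribosome biogenesis (2 of 22 up, 0.0312) and cholesterol synthesis (5 of 13 down, 0.0312) lost their calls, with adjusted p = 0.165, 0.332, 0.698 and 0.694 with an estimated correlation. Without 4 h isotype array 1 the adjusted p was 0.275 for ribosome biogenesis and 0.0628 for cholesterol synthesis, and Ccl17 rose at least 3.85-fold. Foxp3, a CD4 T cell marker (-1.21), and Cd79b, a B cell marker (-0.80), were lower. With array quality weights 3683 genes passed. Normexp background correction gave log2 differences of 5.07 for Ccl3, 5.61 for Irf4, 4.73 for Tnf, 4.07 for Ifng and -3.27 for Ddit4, and the mean of a gene's probes gave -1.02 for Ly9.

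By 18 h of isotype culture, the largest rises against 0 h included effector cytokines, and the largest falls included genes of resting T cells. Ccl3 rose 61.2-fold (SE 0.38, n = 3 and 6, adjusted p = 1.50e-10) from a 0 h mean of 7.20, below the background level, Il2 at least 41.2-fold, Ccl4 by 5.74 on the log2 scale, Ifng by 5.32, Irf8 by 4.75 and the cell cycle inhibitor Cdkn1a at least 31.7-fold. Tsc22d3 (log2 difference -4.44), Klf2, a factor of T cell quiescence (-4.29), Txnip, which restrains glucose uptake (-4.15), Il7r (-4.06) and the integrin Itgb7 (-3.96) fell, as did Scg5 (at least 14.0-fold lower). Ctla4 rose by 1.83 (adjusted p = 9.04e-05), or by 1.14 without 18 h isotype array 3 (adjusted p = 0.000299), and Ptprc fell (-0.89, adjusted p = 0.000786), while Bcl6 did not pass (-0.20, adjusted p = 0.424). The Ptprc value rests on its brightest probe, and its other probes differed by -0.57 (adjusted p = 0.0130) and -0.23 (adjusted p = 0.0736) in limma. Of 4600 genes past the threshold 2367 were higher and 2233 lower, while over 2-fold 617 were higher and 669 lower.

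Naive and quiescence genes had 15 of 18 down and 0 up at 18 h (15 adjusted over the list alone; adjusted p = 1.34e-07, but adjusted p = 0.0900 with an estimated correlation). Proximal T cell receptor signalling genes had 14 of 20 down and 1 up (15 and 1 adjusted over the list alone; Cd3g at -3.16; adjusted p = 1.05e-05, but adjusted p = 0.0581 with an estimated correlation, and 0.0486 without 0 h array 3). Ribosome biogenesis had 19 of 22 up (21 adjusted over the list alone; Odc1 at 3.22) and glycolysis 11 up and 1 down of 16 (Tpi1 at 3.78, Pkm at 2.39), with adjusted p of 1.03e-08 and 7.67e-07, but adjusted p = 0.178 and 0.124 with an estimated correlation. Cytokines (11 up and 2 down of 17), the unfolded protein list (14 and 2 of 24, Asns at 3.99), immediate early genes (12 and 2 of 22), interleukin 2 receptor genes (8 and 2 of 17, Il2ra at 2.99) and migration receptors (3 up and 9 down of 17, Cxcr4 at -3.64) passed as sets, but had adjusted p = 0.0900, 0.166, 0.337, 0.0900 and 0.243 with an estimated correlation. Without 18 h isotype array 3 migration receptors had 1 up and 10 down. S phase genes had 6 of 23 up and 0 down (adjusted p = 0.139), and without that array 7 rose and the list passed (adjusted p = 0.0185, but adjusted p = 0.622 with an estimated correlation). Dendritic cell and myeloid markers had 4 up and 2 down of 18, also adjusted over the list alone, with Lyz1 at least 2.63-fold higher, Cd83 at 0.61, Cst3 at -0.54 and Cd86 at least 1.23-fold lower. Their mean was 7.63 ± 0.13 against 7.43 ± 0.06 at 0 h (adjusted p = 0.348 for the list), and 2 rose and 2 fell without 18 h isotype array 3. Normexp background correction gave log2 differences of 6.79 for Ccl3, 5.98 for Ifng and 5.46 for Irf8, and the mean of a gene's probes gave a rise of at least 15.32-fold for Cdkn1a and log2 differences of -1.62 for Il7r and -3.31 for Tsc22d3.

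After 48 h of isotype culture, 4217 genes differed from 0 h, 2180 higher and 2037 lower. With each array centred on the median of its tested genes 2067 were higher and 2137 lower, with every probe on its own 3327 and 3343, and over 2-fold 514 and 536. Zbtb32, a repressor of T cell activation, rose at least 45.9-fold (SE 0.14, n = 3 and 6), Cdkn1a at least 44.5-fold, Il2 at least 38.4-fold, Bhlhe40 36.0-fold (SE 0.19), Ccl4 by 5.07 on the log2 scale and Ccl3 by 4.86. Klf2 (-4.55), Tsc22d3 (-4.32), Sema4a (-3.91), the kinase Sgk1 (-3.87), Il7r (-3.76) and Nsg2 (-3.57) fell. Ctla4 rose 2.69-fold (adjusted p = 0.00124), Ifng by 3.55 on the log2 scale, and Ptprc was 2.30-fold lower (adjusted p = 4.72e-05). The Ptprc value rests on its brightest probe, and its other probes had smaller log2 differences in limma, -0.51 (adjusted p = 0.0275) and -0.35 (adjusted p = 0.00993). Gzmb, above background on 2 of 3 isotype arrays, rose at least 1.09-fold (adjusted p = 0.000602). Without 48 h isotype array 2 this bound was 0.996, which leaves no rise above the background level. Bcl6 did not pass (-0.32, adjusted p = 0.194). Co-inhibitory receptors had 7 up and 1 down of 10, also adjusted over the list alone, with Lag3 at least 10.9-fold, Cd200 at 2.27 and Btla at 1.04 (adjusted p = 0.00293, but adjusted p = 0.0701 with an estimated correlation). Interleukin 2 receptor genes (9 up and 1 down of 17, Cish at 3.89) and proximal T cell receptor signalling genes (1 up and 13 down of 20, Skap1 at -2.54) passed with adjusted p = 0.0473 each with an estimated correlation. That of the interleukin 2 receptor genes was 0.0694 without 48 h isotype array 2, and that of the proximal signalling genes 0.0631 without 0 h array 2. Without 48 h isotype array 1 co-inhibitory receptors had 7 up and 0 down, with adjusted p = 0.0214 with an estimated correlation.

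Naive genes had 15 of 18 down at 48 h, glycolysis 14 of 16 up and 1 down (Pgk1 at 2.32), cytokines 12 of 17 up and 2 down (Lta at 3.60), and co-stimulatory genes 7 of 14 up and 3 down (Tnfrsf9 at 3.07). These 4 lists had adjusted p from 1.21e-07 to 0.0367, but adjusted p = 0.0701 for each with an estimated correlation (0.0318 for cytokines without 48 h isotype array 1). Dendritic cell and myeloid markers had 6 up and 1 down of 18, also adjusted over the list alone, with Cd83 at 2.31 and Cd74 at 1.39. Their mean was 7.81 ± 0.13, against 7.43 ± 0.06 at 0 h, and they did not pass as a set (adjusted p = 0.135). Ribosome biogenesis (16 of 22 up, Srm at 2.03), immediate early genes (14 up and 1 down of 22), type I interferon genes (10 of 20 down, Ifit3 at -2.89) and G2 and M phase genes (8 up and 1 down of 13, Birc5 at 1.27) passed as sets, but had adjusted p = 0.373, 0.322, 0.438 and 0.707 with an estimated correlation. The rise of G2 and M phase genes rested on 48 h isotype array 1, whose mean was 10.21 beside 8.12 and 7.57 on the other isotype arrays and 7.87 at 0 h. Without it 3 rose and 1 fell (median 0.25, with 1.03 in all arrays; adjusted p = 0.743), and Birc5 was at 0.28 (adjusted p = 0.106). The call of this list also ended without 0 h array 2, 3, 4 or 6, with adjusted p of 0.0503 to 0.0528. Without 48 h isotype array 1, type I interferon genes had 2 up and 7 down (adjusted p = 0.233) and ribosome biogenesis 10 up. Cdkn1a rose at least 73.0-fold and Il2 at least 23.6-fold without it, and the log2 difference was 4.13 for Ccl3, 2.85 for Ifng and -3.87 for Klf2 (-5.16 without isotype array 2). Probes of Cd8b1 disagreed (0.54, -1.64 and -1.85), as did those of Bcl2l11 (0.19, -0.43 and -0.88). Normexp background correction gave 5.70 for Ccl3, 4.17 for Ifng and 5.92 for Bhlhe40, and the mean of a gene's probes gave rises of at least 11.9-fold for Zbtb32 and 19.3-fold for Cdkn1a and log2 differences of -1.54 for Il7r, -2.09 for Nsg2 and -3.25 for Tsc22d3.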

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

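The tests on 18 h isotype array 3, and the test of 48 h isotype array 1 as an 18 h sample, were chosen only after the result was seen; the tests on array noise, on dendritic cell RNA and on other splits of the arrays were set before.

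The FcMR effect differed between 4, 18 and 48 h for 1912 of 9168 genes, by the moderated F test of limma. In 100 splits drawn within each time, only the real split gave as many (highest other 1470). These splits remove the whole FcMR effect, so they cannot tell a difference between times from an effect that the times share. Without 18 h isotype array 3 the count was 2621. Among the 50 genes named for FcMR, 36 had such a difference between times, beside 20.9% of all genes. Many of them were named for a large effect at a single time, which favours such a difference. None of 31 genes tested had an array far from the others at 0 h. The figures that follow are the spread between the highest and the lowest effect of the 3 times, on the log2 scale. The effect was highest at 4 h for Rsad2 (4.598), Usp18 (3.60), Eif2ak2 (3.86), Isg20 (3.68), Mx2 (4.89), Dhx58 (3.53), Rgs1 (4.95), Cxcl10 (3.43), Gbp5 (2.25), Lif (2.58), Ifng (3.15), Chac1 (2.15), Lrmp (1.56) and Ccl3 (2.56). It was lowest at 4 h for Fam78a (2.97), Sesn1 (2.08), Rassf2 (2.39), Cnr2 (1.81), Bambi-ps1 (1.67), Il16 (1.58), Bcl6 (1.198) and Ap2s1 (0.80). It was highest at 48 h for Tgm2 (3.22), Egln3 (2.95), Ndrg1 (3.52), Ier3 (3.57), Mgarp (2.37), Dennd11 (2.68) and Tomm40l (1.73). It was lowest at 48 h for Cd160 (2.12), Osr2 (2.48), Glipr1 (3.20), Phlda1 (2.01), Gtse1 (3.31), Il2 (2.01) and Acad8 (0.61). Chac1, Lrmp and Ccl3 had 4 h effects of only 0.17, 0.02 and 0.32, so their spread came from later falls. Ap2s1 was at -0.02 at 4 h and Acad8 at -0.11 at 48 h, so their spread came from rises at 18 h.

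The 18 h isotype array 3 lay with the FcMR arrays. Over 320 genes that passed with more than a 2-fold change without this array, its median position was 0.951 on a log2 scale from 0 (isotype arrays 1 and 2) to 1 (FcMR). Each FcMR array was placed against the other two in the same way, over 270 to 298 genes that passed with more than a 2-fold change without it and without isotype array 3. The lowest FcMR position was 0.938, which argues against an exchange with an FcMR array. The result also argues against a mixture of both RNAs, since the position on unlogged values was also 0.951. A candidate explanation is an FcMR sample under the isotype label. A culture with isotype control that took the course of the FcMR cultures was not tested and stays open too.

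The 48 h isotype array 1 was high in cell division genes and low in interferon genes. On 256 genes it lay over 0.5 log2 beyond all other 23 arrays (185 higher, such as Pclaf at 11.38 against at most 7.47 elsewhere, and 71 lower, such as Irf7 and Usp18), while 18 h isotype arrays did so on at most 19, which argues against an 18 h isotype sample under this label, although over 797 genes its median position was 0.735 (quartiles 0.43 and 0.987) from the other 48 h isotype arrays at 0 to 18 h isotype arrays 1 and 2 at 1. Its spread over probes never above background was 0.921 times the highest of the other arrays, so these probes showed no extra noise. A probe that noise lifted above background on any array is left out of this test. Noise among expressed genes was not examined, so a noisier array stays open. A culture with more dividing cells and a sample from outside the labelled groups may each account for it, and neither was tested.

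Type I interferon genes rose with FcMR at 4 h by a median of 2.44 log2 while myeloid markers rose by 0.21. If the rise were more carry-over of the dendritic cell RNA that the isotype arrays hold, it would be 0.01, which leaves 2.43 unaccounted for and argues against that source. RNA of dendritic cells with induced interferon genes could not be excluded: the median unlogged rise of the interferon genes was 1.52 times the highest level of a myeloid marker dim at 0 h (Lyz1), too near for either reading, although the cells were sorted as CD8+. The rise is consistent with an interferon response of the T cells to FcMR, or of the dendritic cells, and the test cannot separate these.

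For the count at 4 h the highest of the other splits gave 123 genes against the real 1281, and at 48 h 225 against 1792, each with the real one as 1 of 10 splits, which are too few for a share under 0.05. At 18 h the real count was 0 (highest other 6), which all 10 splits reach by construction, so that comparison says nothing about chance. For the mean effect 1 of 100 drawn splits, the real one, reached 1544 (highest other 728), and for any time 1 of 100 reached 2763 (highest other 1834). This argues against chance only if the arrays are independent, which the labels do not state. For isotype against 0 h, 1 of 84 splits, the real one, gave as many genes at 4 h (2067, highest other 420), 18 h (4600, highest other 446) and 48 h (4217, highest other 557). These splits also take the arrays as independent. The 0 h arrays 1, 4 and 6 lay together, as did arrays 2, 3 and 5. Across genes, r was 0.9898 to 0.9936 within and 0.9772 to 0.9813 between these sets, so chance is not excluded here.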

How the results depend on the processing

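Normexp background correction, the stricter filter, centring of each array on the median of its tested genes and leaving out both arrays that stood apart were chosen after seeing the data; all other settings were planned. Values of named genes were computed under each setting except array quality weights, the trend and robust variance priors and the 2-fold threshold, under which only counts of genes were made. Of these values 897 kept their direction and side of the threshold, 9 lost a call, 1 gained one and 1 reversed. With 1 array left out, 992 kept them, 6 lost a call and 1 gained one. These counts cover only named genes past the threshold in the fit of all arrays, and Ctla4 and Ptprc for FcMR. Gains of other named genes were therefore not counted, such as Ifng at 18 h without 18 h isotype array 3 (adjusted p = 0.00706 in limma). Chac1 and Lrmp at 18 h without that array, and Ifng at 48 h without 48 h isotype array 1, are further examples. List tests were run only with no filter, normexp correction, the replicate block, both arrays left out and an estimated correlation, and only for lists past the threshold for FcMR, so that gains could not be seen. There 153 kept and 37 lost the call, 27 of them with the estimated correlation, and with 1 array left out 321 kept and 51 lost it. With 1 array left out of the groups compared, 15 other list tests for FcMR gained a call, such as type I interferon genes at 48 h, and for isotype against 0 h 8 lost and 3 gained one, such as ribosome biogenesis at 4 h (lost) and S phase genes at 18 h (gained). The reversed value was Ptprc at 18 h, -0.037 with the mean of a gene's probes, passing in neither. Its brightest probe was at 0.148 and its other probes at -0.167 and -0.091, so the sign depended on the probe. Testing every probe on its own, which tests more items, gave 1968 at 4 h, 2877 at 48 h, 2443 for the mean effect, 4272 at any time, 2885 that differed between times, and 7427 and 6670 for isotype at 18 and 48 h against 0 h. Array quality weights gave 2213 at 4 h, 2627 at 18 h, 2997 for the mean effect, 5039 at any time, 3926 that differed, and 3683 for isotype at 4 h; the lowest weights were 0.106 for 48 h isotype array 1, 0.215 for 4 h FcMR array 2 and 0.248 for 18 h isotype array 3. Only the arrays compared gave 572 at 48 h, and the replicate block gave 1248 that differed; the causes were not tested. Adding a 2-fold threshold, stricter by construction, left 323 at 4 h, 341 at 48 h, 46 for the mean effect, and 311, 1286 and 1050 for isotype at 4, 18 and 48 h. Without both arrays the counts were 1953 at 18 h, 2516 for the mean effect, 4379 at any time and 3451 that differed, with Ctla4 at 18 h at 2.15. With 1 array of the groups compared left out in turn, the 18 h count ranged from 0 to 1379 and Ctla4 at 18 h from 1.09 to 2.15 (adjusted p = 8.71e-06 at the upper end, without isotype array 3), the 4 h count from 859 to 1197 and the 48 h count from 1203 to 2188. Under the other settings run the 18 h count was 0. Replicate numbers did not pair arrays: the correlations across genes of isotype and FcMR deviations with the same number were -0.25, -0.42 and 0.53 at 4 h, and between -0.14 and 0.19 at 18 and 48 h. With different numbers at 4 h they ran from -0.587 (isotype array 1 and FcMR array 3) to 0.529 (isotype array 1 and FcMR array 2). A pairing or batch that the numbers do not carry is therefore not excluded. Settings based on neqc, detection p-values and the BeadChip were not run, and a replicate block could not be fitted for isotype against 0 h. Signal over background limits the folds of dim genes, which normexp correction raised.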

Other observations

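Both list tests described first were chosen only after the result was seen, while the comparison with the course of the isotype cells was set before, although its criterion was made stricter after its value was seen.

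Genes that respond to low oxygen were higher with FcMR at 48 h. Of 29 tested members of a list written after the 48 h genes had been seen, 19 rose and 0 fell, with P4ha2, a collagen hydroxylase, at 2.32, the angiogenic factor Vegfa at 1.73, the lipid droplet gene Hilpda at 1.73 and the glycolytic aldolase Aldoc at 1.89. With Egln3, Ndrg1, Eno2 and Mgarp left out, the members among the largest FcMR changes, 15 of 25 rose (adjusted p = 0.0181 with an estimated correlation), and without 48 h isotype array 1 14 rose and 1 fell (0.0479). With all 11 members left out that the rule for naming genes picked in any comparison of all arrays, 10 of 18 rose (0.0193), and without that array 10 rose and 1 fell (0.0339). The rule picked P4ha2 only with that array left out. With P4ha2 left out as well, 9 of 17 rose (0.0288), and without that array 9 rose and 1 fell (0.0368). Vegfa, Hilpda and Aldoc are among these 17. The list shares 8 tested genes with the glycolysis list. At 18 h 0 of 29 passed, and without 18 h isotype array 3 15 rose and 0 fell (adjusted p = 0.0215 with an estimated correlation). These values are consistent with a joint response of hypoxia genes to FcMR at 48 h, as a hypothesis from the same data.

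Targets of the tumour suppressor p53 took the opposite direction at 48 h. Of 28 tested members, 0 rose and 11 fell with FcMR, among them Ppm1d (-1.57), Plk2 (-1.50), Mdm2 (-1.45) and Phlda3 (-1.28) (median -0.64, adjusted p = 0.189 with an estimated correlation), and without 48 h isotype array 1 0 rose and 20 fell (median -1.27, adjusted p = 0.0437 with an estimated correlation). Isotype cells at 48 h had 22 up and 3 down against 0 h (adjusted p = 0.138 with an estimated correlation). The set test was open: with Sesn1 and Gtse1 left out, the members among the largest FcMR changes, the adjusted p was 0.212 with an estimated correlation, and 0.0504 without 48 h isotype array 1. With all 5 members left out that the rule for naming genes picked in comparisons of all arrays, it was 0.158, and 0.0339 without that array. With Phlda3 and Zfp365 left out as well, which the rule picked only with an array left out, it was 0.159, and 0.0368 without 48 h isotype array 1. At 18 h the median difference was 0.74 with 0 past the threshold, and without 18 h isotype array 3 20 rose and 0 fell (adjusted p = 0.034 with an estimated correlation).

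Across genes, which are not independent replicates, the FcMR effect at 4 h correlated with the change of isotype cells from 0 h to 18 h (r = 0.364, and 0.385 without type I interferon genes). That would be consistent with a further step along the course of the isotype cells, and the value meets the criterion as first set. Another of the 10 splits of the 6 arrays reached 0.505 in size, so the test cannot tell.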
